A study of Homo sapiens with 8 samples.

How the data were processed

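Binding sites of G3BP1, an RNA-binding protein of stress granules, were mapped by seCLIP (single-end enhanced crosslinking and immunoprecipitation) in HEK293T, an established human embryonic kidney cell line. In this assay RNA is crosslinked to protein by UV light, the protein is immunoprecipitated (IP), and the recovered RNA fragments are sequenced beside a matched input library made without the antibody. The 8 libraries form 4 groups with 2 replicates each: IP and input from untreated cells (Ctrl), and IP and input from cells given 20 µM PDS for 12 h before crosslinking. The labels do not spell out PDS; in work on guanine quadruplexes it usually stands for pyridostatin, a small molecule that binds and stabilises these structures.

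What was deposited and analysed here is 1 peak list per condition, named as replicate 1 against replicate 2, so that the authors combined the replicates before deposit. Per the submitters' processing notes, reads were handled with cutadapt, UMI-tools and STAR, and the build was hg19. The peak caller, its filters and the way replicates were combined are not given in the sources used here. Each list has 6 columns without a header: chromosome, start, end, 2 values per peak and strand. The first value was read as the −log10 p of the peak as deposited by the authors; its highest value was 400 in both lists, with no value between 87.9 and 400, so that 400 was read as a stand-in and not as a measured value. The second value was read as the authors' deposited log2 fold enrichment of IP over input. Both readings are inferred from the values and from the usual eCLIP peak format, in which log2 fold and −log10 p are cut at 3. Every deposited peak had a log2 fold above 3 and a −log10 p above 3. Starts were treated as counted from 0, because adjacent peaks share a border coordinate, and coordinates are printed counted from 1.

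Read totals of the libraries were not analysed here, so the depth behind a peak is unknown, and no value exists per replicate. Nothing in the lists measures the spread between replicates, and differences between the conditions therefore carry no replicate test. Exact (Clopper-Pearson) 95% binomial intervals beside shares of peaks cover counting error only, and neighbouring peaks are not independent. Nothing in the labels says whether replicates came from separate cultures.

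Overlaps were computed with bedtools 2.31.1 (python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). A peak was shared if at least 1 nt lay in a peak of the other list on the same strand. As a comparison level, PDS peaks were shifted along their strand in steps to 2000 nt in both directions, and overlaps on the opposite strand were counted. Neighbouring peaks were joined into regions by merging same-strand peaks within 50 nt. Peaks of both lists were also chained over same-strand gaps of up to 10000 nt into loci, which stand in for transcription units; a locus may hold several genes or part of 1 gene. This grouping was chosen after the lists had been seen. Ratios of the lists have 95% bootstrap intervals from 10000 resamples of the loci, which cover the spread between loci and not between replicates. Within each list, the log2 fold of shared and unshared peaks was compared by a two-sided permutation test of the difference in medians with 100000 resamples. The same comparison within single loci used sign flips. Chromosomes were compared by Fisher's exact test on loci found in 1 list alone, with Benjamini-Hochberg adjustment over 23 chromosomes.

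The scripts were tested on simulated data. All 400 copies of Ctrl peaks planted in a simulated list were found, and 0 peaks differed from a brute-force search. With the peaks of the Ctrl list assigned to groups at random, 3% of 100 draws gave a permutation p under 0.05, and 100% did so with a planted log2 difference of 0.2; for the PDS list these shares were 7% and 100%. The within-locus test gave 5% and 99% for the Ctrl list and 4% and 100% for the PDS list. In all these draws the groups were assigned at random peak by peak. The rates therefore do not show how the tests behave when neighbouring peaks are shared together.

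The gene-based parts of the design could not be carried out as written. An hg19 genome or annotation was not used here, and builds were not mixed, so peaks were not assigned to genes or transcript regions, the gene lists fixed beforehand were not tested, and the sequences were not searched for quadruplex motifs. The comparison of enrichment between conditions at shared peaks was not made, because it needed values per replicate. The rule for named items, fixed before the data were examined, was applied to peaks and loci in place of genes: in each list the 10 peaks with the highest log2 fold, 1 per locus, and the 5 loci with most peaks. The parts of the rule that need gene names, sequences or values per replicate were not applied. Alternatives were a stricter threshold (−log10 p of at least 5 and log2 fold of at least 4), other definitions of sharing, a PDS list shortened to the length of the Ctrl list, and other definitions of a locus.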

Results

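G3BP1 binding sites were compared between untreated HEK293T cells and cells given PDS. The untreated (Ctrl) list held 1421 peaks and the PDS list held 2925 peaks, each list combining 2 IP replicates against their inputs. Peaks lay on 23 chromosomes in both lists, with 0 peaks on the mitochondrial genome or the Y chromosome in either. Chromosome 19 held the most Ctrl peaks (157, 11.0% of the list) and the second most PDS peaks (253, 8.65%), behind chromosome 1 (302 PDS peaks, 10.3%). Chromosomes 13, 18 and 21, which are poor in genes, held 5, 6 and 5 Ctrl peaks and 9, 12 and 26 PDS peaks. The minus strand carried 56.0% of Ctrl peaks (95% interval 53.4 to 58.6%) and 54.2% of PDS peaks (52.3 to 56.0%). Fold and p values below are the authors' own for each peak, 1 value for both replicates together, and carry no SD.

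Ctrl peaks had a median width of 74 nt (quartiles 50 and 102 nt) and covered 112841 nt. PDS peaks had a median width of 63 nt (quartiles 35 and 93 nt) and covered 196589 nt. Many peaks abutted another: 158 Ctrl peaks (11.1%) and 693 PDS peaks (23.7%) began at the border where the previous peak ended. Whether abutting peaks are pieces of a longer bound stretch was not tested. After merging within 50 nt, 1176 Ctrl regions with a median width of 85 nt and 2036 PDS regions with a median width of 87 nt remained. The median log2 fold enrichment over input was 3.52 in the Ctrl list (quartiles 3.24 and 3.93, highest 6.47) and 3.59 in the PDS list (quartiles 3.26 and 4.06, highest 6.31). The −log10 p was 400 in 8 Ctrl peaks and 82 PDS peaks, and the next highest values were 87.3 and 87.9.

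The first question was how many sites G3BP1 occupied with and without PDS. The PDS list held 2.06 times as many peaks as the Ctrl list (95% bootstrap interval over loci 1.90 to 2.23), 1.73 times as many merged regions (1.60 to 1.87) and 1.42 times as many loci (1.33 to 1.53), 950 against 667. At higher minimums of enrichment the ratio varied. At a log2 fold of at least 4 there were 313 Ctrl and 808 PDS peaks, a ratio of 2.58, at least 4.5 was reached by 119 and 350, a ratio of 2.94, at least 5 was reached by 38 and 105 peaks, a ratio of 2.76, and at least 5.5 by 11 and 17, a ratio of 1.55. With 1 combined list per condition, these ratios could not be tested against the spread between replicates.

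**Figure D1:**
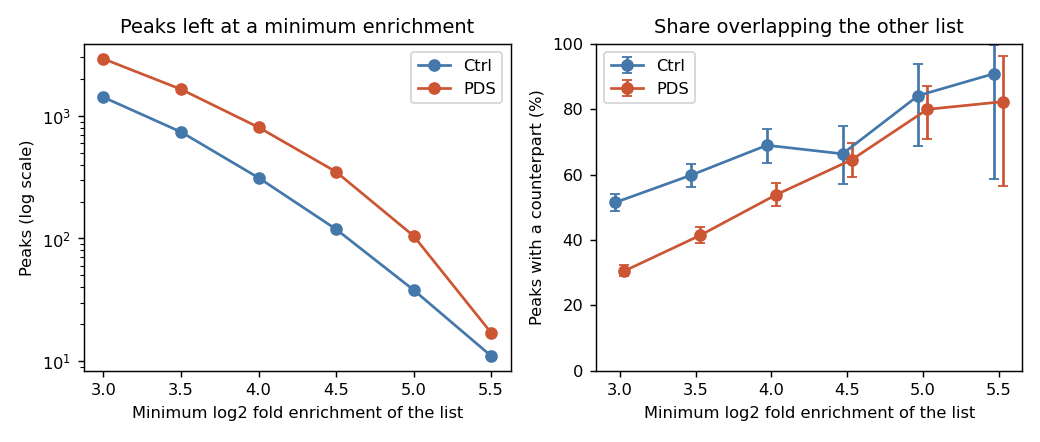
Left, number of peaks in the Ctrl and PDS lists (log axis) that reach each minimum log2 fold enrichment (x axis); right, percent of those peaks that overlap a peak of the other whole list, with exact 95% binomial intervals as bars. The PDS list is longer at every minimum shown, and the overlapping share is 51.5% of Ctrl and 30.6% of PDS peaks at a minimum of 3 and 84.2% and 80.0% at a minimum of 5.

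The second question was whether the same sites were occupied. Of the 1421 Ctrl peaks, 732 overlapped a PDS peak on the same strand, a share of 51.5% (95% interval 48.9 to 54.1%). Of the 2925 PDS peaks, 894 overlapped a Ctrl peak, a share of 30.6% (28.9 to 32.3%). The overlap covered 47980 nt, which is 42.5% of the bound length in the Ctrl list and 24.4% of that in the PDS list. On the opposite strand, 0 peaks overlapped, with an exact 95% upper bound of 0.259% of Ctrl peaks. When the PDS peaks were shifted by 500 to 2000 nt along the strand, between 44 and 93 Ctrl peaks were hit (3.10 to 6.54%). The unshifted overlap was 7.87 times the highest shifted one. Shifts were made in genome coordinates without annotation, so shifted peaks may have left the bound transcripts. Neither the shifts nor the opposite strand give the overlap expected among unrelated sites of the same transcripts. Sharing was set by its definition to some degree: requiring that each peak cover at least 50% of the other left 40.0% of Ctrl and 19.5% of PDS peaks shared, and shortening the PDS list to its 1421 most enriched peaks left 36.3% of Ctrl and 44.0% of those PDS peaks shared, turning the order of the lists.

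**Figure D2:**
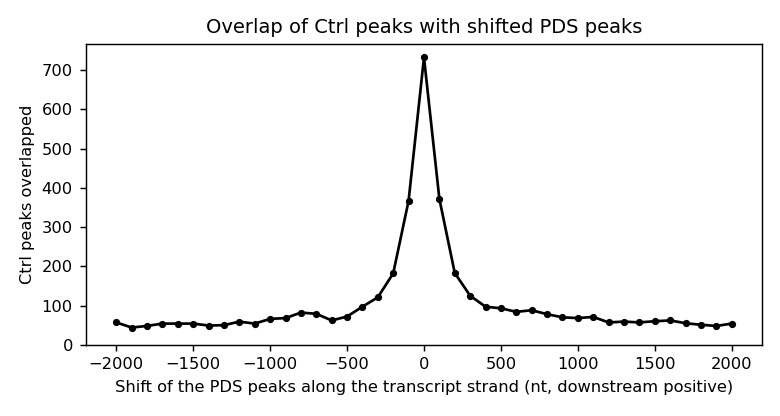
Number of Ctrl peaks (y axis) that overlap a PDS peak on the same strand after all PDS peaks are moved along their strand by the distance on the x axis (nt, downstream positive). The count is 732 at 0 nt, 367 and 372 at 100 nt upstream and downstream, and at most 93 from 500 nt onward.

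Exactly 1 Ctrl peak met exactly 1 PDS peak in 410 pairs, which were selected by their overlap. The midpoints lay within 10 nt of each other in 250 of them (61.0%), where 16.8% would be expected if every overlapping placement of the same widths were equally likely, a comparison chosen after the pairs had been seen. The PDS midpoint lay downstream in 210 pairs, upstream in 186 and at the same position in 14, with a median offset of 0.5 nt, and an exact two-sided sign test gave p = 0.248 over peak pairs. The median width was 80.5 nt in both lists for these pairs.

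Shared peaks were the more strongly enriched ones in each list. In the Ctrl list the median log2 fold was 3.63 for the 732 shared peaks and 3.43 for the 689 others, a difference of 0.19 (two-sided permutation test, p = 1e-05, the smallest the resamples can give). In the PDS list the medians were 3.97 for 894 shared and 3.47 for 2031 other peaks, a difference of 0.50 (permutation p = 1e-05, again the smallest possible). These tests compare peaks within 1 list, and peaks are not independent replicates. Within single loci that held both kinds of peak, shared peaks were higher in 74 of 119 loci of the Ctrl list, by a mean of 0.13 ± 0.04 (SE; sign-flip permutation p = 0.00385), and in 135 of 187 loci of the PDS list, by 0.24 ± 0.04 (SE; permutation p = 1e-05).

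Chained into loci, the peaks of both lists fell into 1192 stretches of the genome, of which 425 held peaks in both lists, 242 in the Ctrl list alone and 525 in the PDS list alone. Thus 63.7% of Ctrl loci (95% interval 59.9 to 67.4%) and 44.7% of PDS loci (41.5 to 48.0%) held peaks of the other list. In the 425 loci in common, the PDS list had more peaks in 227, as many in 143 and fewer in 55; by merged regions it had more in 167, as many in 206 and fewer in 52. Of the 2031 unshared PDS peaks, 1083 (53.3%, 51.1 to 55.5%) lay in loci that also held a Ctrl peak and 948 in loci that held none. Of the 689 unshared Ctrl peaks, 397 (57.6%, 53.8 to 61.3%) lay in loci that held a PDS peak.

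A few loci carried many peaks. The 10 loci with most peaks held 14.4% of Ctrl peaks and 13.0% of PDS peaks, whereas 430 of 667 Ctrl loci (64.5%) and 491 of 950 PDS loci (51.7%) held a single peak. The same 3 loci led both lists (coordinates in hg19). The minus strand of chromosome X from 153577052 to 153596260 held 43 Ctrl and 72 PDS peaks, which merged into 30 and 32 regions. The minus strand of chromosome 8 from 144990307 to 145008211 held 32 Ctrl and 48 PDS peaks, merging into 26 and 19 regions. The plus strand of chromosome 3 from 184017025 to 184053095 held 27 and 41 peaks, merging into 20 and 22. Next in the Ctrl list came the minus strand of chromosome 17 from 80036498 to 80049172, with 19 Ctrl and 29 PDS peaks, and the plus strand of chromosome 16 from 30077137 to 30087754, with 17 and 21. Merging turned the direction in the chromosome 16 locus too (10 Ctrl and 8 PDS regions), as it had in the chromosome 8 locus. Next in the PDS list came the minus strand of chromosome 20 from 17595394 to 17617322, with 10 Ctrl and 33 PDS peaks, and the minus strand of chromosome 1 from 226549713 to 226595773, with 12 and 33; a chromosome 22 locus tied at 33 PDS peaks and ranked below them by highest fold.

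**Figure D3:**
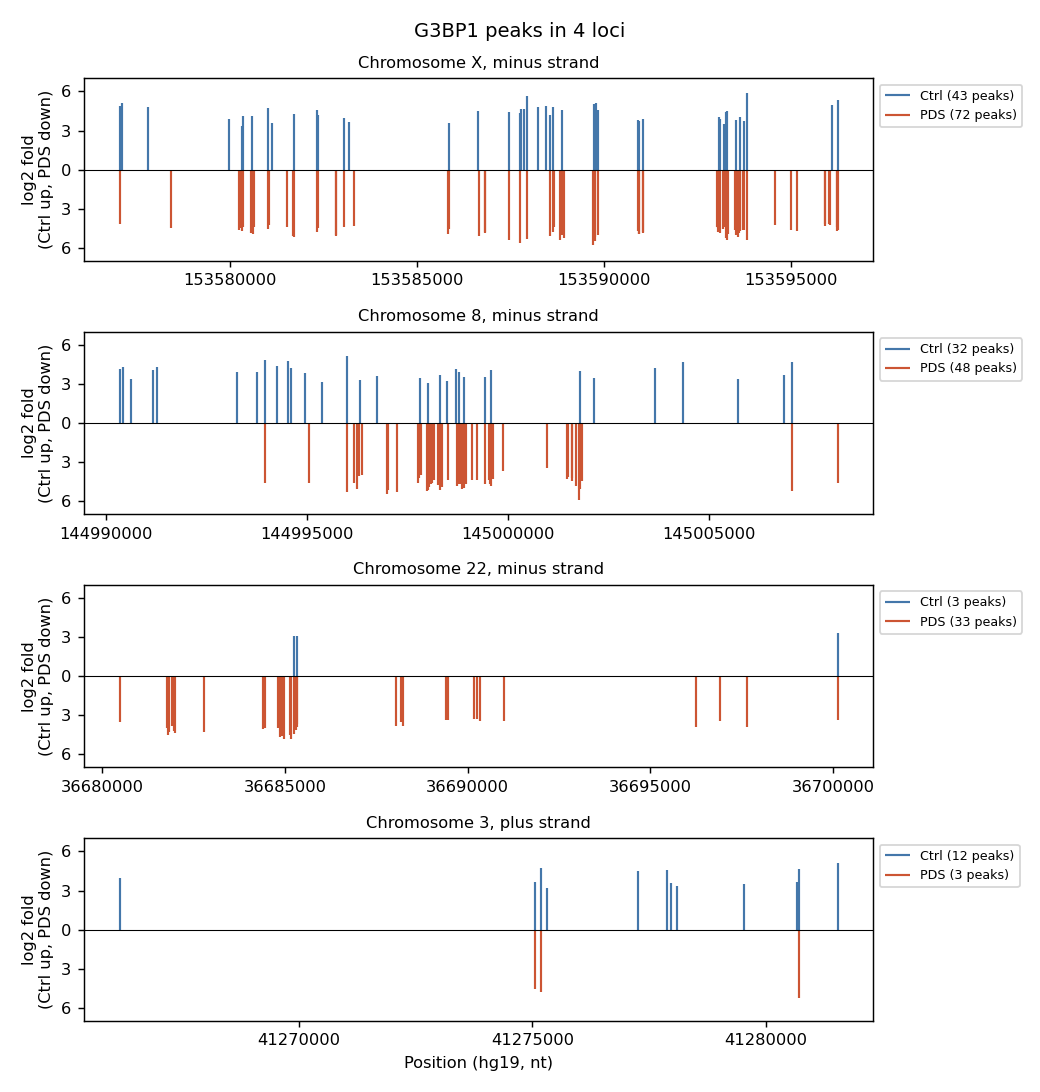
Peaks along 4 loci by hg19 position (x axis, nt), each drawn as a line at its midpoint whose length is its log2 fold enrichment, Ctrl upward and PDS downward. The upper panels are the loci with most peaks in both lists (chromosomes X and 8); the lower panels are a locus with the largest excess of peaks in PDS (chromosome 22, 3 against 33, tied with a chromosome 9 locus at 2 against 32) and the one with the largest excess in Ctrl (chromosome 3, 12 against 3), chosen after the counts were seen.

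The most enriched Ctrl peak was 2 nt long, on the minus strand of chromosome 8 at 99057736 to 99057737, with a log2 fold of 6.47. It belonged to a run of 5 Ctrl and 4 PDS peaks, and the most enriched PDS peak of that run, at 99057738 to 99057756, had a log2 fold of 5.49. The next Ctrl peaks lay on chromosome 19 at 59060788 to 59060934 (plus strand, log2 fold 5.94), on chromosome X at 153593785 to 153593854 (minus strand, 5.85) and on chromosome X at 112022370 to 112022487 (minus strand, 5.56). They were followed by chromosome 8 at 48711838 to 48711947 (minus strand, log2 fold 5.56), chromosome 3 at 184052822 to 184052915 (plus strand, 5.53) and chromosome 16 at 30080629 to 30080706 (plus strand, 5.49). The last of the 10 were chromosome 17 at 80036538 to 80036630 (minus strand, log2 fold 5.45), chromosome 1 at 220267512 to 220267668 (plus strand, 5.44) and chromosome 14 at 103986096 to 103986124 (minus strand, 5.32). The peaks on chromosomes 17 and 14 overlapped no PDS peak, although their loci held 29 and 7 PDS peaks. The other 8 overlapped a PDS peak.

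The most enriched PDS peak lay on the plus strand of chromosome 2 at 54880802 to 54880909, with a log2 fold of 6.31, in a locus with 14 Ctrl and 26 PDS peaks. A neighbouring locus on the same strand held the fourth-ranked peak, at 54856176 to 54856193 (log2 fold 5.79), with 13 Ctrl and 22 PDS peaks around it. The second-ranked peak lay on chromosome 20 at 2444451 to 2444542 (minus strand, log2 fold 5.92), in a locus with 3 PDS peaks and 0 Ctrl peaks. The third lay on chromosome 8 at 145001728 to 145001778 (minus strand, 5.89). Then came chromosome 3 at 184052534 to 184052586 (plus strand, log2 fold 5.76), chromosome X at 153589688 to 153589745 (minus strand, 5.76) and chromosome 1 at 220267531 to 220267707 (plus strand, 5.59). The last 3 were chromosome 11 at 66456203 to 66456320 (minus strand, log2 fold 5.58), the chromosome 8 peak at 99057738 to 99057756 named above (5.49) and chromosome 12 at 6691340 to 6691415 (minus strand, 5.40). Of these 10 peaks, those on chromosomes 20 and 11 overlapped no Ctrl peak; the chromosome 11 locus held 7 Ctrl and 15 PDS peaks.

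The chromosomes of loci found in 1 list alone were compared last. None of the 23 chromosomes differed between the 242 Ctrl-only and the 525 PDS-only loci at an adjusted p under 0.05 (Fisher's exact test, Benjamini-Hochberg adjustment), and 4 did at an unadjusted p under 0.05. The smallest adjusted value, 0.0605, was reached by chromosome 22, with 7.44% of Ctrl-only and 2.67% of PDS-only loci, and by chromosome 6, with 9.92% and 4.38%.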

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

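Of 39 alternative values, 19 stayed close to the main one and 20 moved. Close means within 1.5 times for counts and ratios, within the main 95% interval for percentages, which is narrower, and on the same side of 0 and of 0.05 for tests. The alternatives on merging for the overlap, on the loci with most peaks and on the definition of a locus were chosen after seeing the data, as was the test within loci. The stricter threshold left 313 Ctrl and 808 PDS peaks, the same as its log2 fold limit alone. The PDS to Ctrl ratio was 1.73 with merged regions and 2.58 with the stricter threshold. The shared percentage of Ctrl and PDS peaks was 40.0 and 19.5 with reciprocal overlap of 50%, 58.1 and 36.9 within 100 nt, 45.4 and 21.5 with the stricter threshold in both lists, and 36.3 and 44.0 with the PDS list at the Ctrl length, which turned the order of the lists. For PDS peaks it was 28.1 with merged regions and 27.8 without the 7 loci that are among the 5 with most peaks in either list. Loci in both lists, in Ctrl alone and in PDS alone numbered 91, 72 and 177 with the stricter threshold, and 514, 382 and 972 with gaps of up to 1000 nt. With gaps of up to 50000 nt they numbered 407, 184 and 402. When a list was counted in a locus only if it held at least 2 peaks there, the numbers were 161, 76 and 298. In that setting a locus counted for 1 list could still hold 1 peak of the other. Shared peaks stayed above the others in both lists in each alternative tried, with the permutation p on the same side of 0.05. The causes of these moves were not tested, except that stricter limits leave fewer peaks. The usual eCLIP limit of 3 could remove no peak, because every deposited peak already lay above it, so it is no check of the results. No paired analysis was possible because the lists give 1 value per peak for both replicates together; for the same reason no replicate could be left out. The comparisons planned on genes, gene lists, transcript regions, quadruplex patterns and enrichment at shared peaks were not run. The depth behind a peak is unknown, which limits any statement on peaks missing from a list.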

Other observations

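The tests by bins of fold, of PDS peaks within 100 nt and of Ctrl peaks past the stricter threshold were chosen after the results they measure had been seen, and so was the use of the merged ratio against splitting, although that ratio was set beforehand as an alternative; the test within loci was chosen after the data had been seen but before its own result. The loci with the largest excess of peaks in either list were picked after their counts were known and have no replicate test. In PDS these were the minus strand of chromosome 22 from 36680454 to 36700157, with 3 Ctrl and 33 PDS peaks (2 and 16 merged regions), and the plus strand of chromosome 9 from 131339139 to 131381216, with 2 and 32 peaks (2 and 22 regions), tied in their excess. They were followed by the chromosome X locus named in the report, with 43 and 72 peaks (30 and 32 regions). The minus strand of chromosome 10 from 120796722 to 120809368 held 1 Ctrl and 25 PDS peaks, but only 1 and 6 merged regions. In Ctrl the largest excess was on the plus strand of chromosome 3 from 41266111 to 41281583, with 12 Ctrl and 3 PDS peaks (10 and 2 regions). Second was a 70-nt stretch on the plus strand of chromosome 5 from 138614483 to 138614552, with 6 Ctrl peaks in 1 merged region and 0 PDS peaks.

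Among loci of 1 list alone, those with most peaks in PDS lay on the minus strand of chromosome 17 from 8383768 to 8416932 (16 peaks, highest log2 fold 3.76), the minus strand of chromosome 2 from 232319917 to 232327912 (14 peaks, 4.06) and the plus strand of chromosome 1 from 151495927 to 151508099 (13 peaks, 4.85). In Ctrl, after the chromosome 5 stretch, they were the minus strand of chromosome 12 from 49435078 to 49445508 (4 peaks, highest log2 fold 3.58) and, tied at 3 peaks, the plus strand of chromosome 22 from 24236593 to 24237119 (highest log2 fold 3.98) and the minus strand of chromosome 22 from 29736696 to 29745348 (3.64). The most enriched peak in a Ctrl-only locus lay on the minus strand of chromosome 1 at 149857735 to 149857834 (log2 fold 5.11), and that in a PDS-only locus on chromosome 20 at 2444451 to 2444542 (5.92).

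The first pattern weighed is the longer PDS list. Splitting of bound stretches into adjacent pieces is argued against as the whole cause, since the ratio of merged regions was 1.73 with a lower bootstrap bound of 1.60, down from 2.06 before merging. A larger number of reads behind each peak in the PDS list remains open and is in line with the test made for it: in 7 of 7 bins of log2 fold, the median −log10 p was higher in the PDS list, by 1.27 to 1.42 times, for example 10.3 against 7.28 in the lowest bin. At a matched fold, −log10 p grows with the number of reads, so deeper libraries or more recovered RNA could lengthen the PDS list. By which filter they would do so is not shown, since the lowest −log10 p was 3.66 in Ctrl and 4.31 in PDS, above the usual limit of 3. The ratio of peaks was 2.94 at a log2 fold of at least 4.5 and 1.55 at a log2 fold of at least 5.5. The higher −log10 p at a matched fold could also come from closer replicates if the deposited value is the lower of both. How the replicates were combined is unknown, so the bins are not a measure of depth alone. An increase in G3BP1 binding after PDS was not tested as an explanation. Each condition has 1 list, and the depth and RNA recovery behind it are unknown.

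The second pattern is that 689 Ctrl peaks had no PDS peak although the PDS list was longer. Differently placed borders may account for a minority, since 13.6% of them (95% interval 11.2 to 16.4%) had a PDS peak within 100 nt. Weakness near the authors' limit was tested on the 313 Ctrl peaks past the stricter threshold. Of these, 97 (31.0%, interval 25.9 to 36.4%) still had no PDS peak. Overlapping peaks could differ by more than the margin of that threshold, for example a log2 fold of 5.49 in Ctrl and 3.79 in PDS on chromosome 16. The test therefore cannot decide whether weakness is the whole cause. At log2 fold minimums of 5 and 5.5, 84.2% of 38 and 90.9% of 11 Ctrl peaks had a PDS peak. Below the stricter threshold the share without a PDS peak was higher than past it, 53.4% of 1108 Ctrl peaks (Fisher's exact test over peaks, p = 1.96e-12), so strength is related to sharing. Neighbouring peaks are not independent, so that p may be too small. The comparison also repeats, in another form, the one of shared and other Ctrl peaks. Loss of binding after PDS and disagreement between replicates stay open as untested, because the lists give no value per replicate.

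The third pattern is the stronger enrichment of shared peaks. If it arose only because some loci are both stronger and richer in peaks, no difference would be left within loci, a prediction written before the result was seen. A difference remained in both lists, with a mean log2 fold difference of 0.24 within 187 loci of the PDS list and 0.13 within 119 loci of the Ctrl list, which argues against differences between loci as the whole cause. Because a locus may hold several genes, differences between transcripts inside a locus were not tested. Whether stronger peaks are shared because they are detected more reliably or because their occupancy depends less on PDS stays untested.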
